A study of Rattus norvegicus with 4 samples.

How the data were processed

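The series holds 4 samples of rat NR8383 cells taken at 24 h, 1 for vehicle control and 1 for each of 3 kinds of submicron carbon fibres (SCF1, SCF2 and SCF3) at 10 µg/mL. Each sample came with 4 scanner files, 1 per Agilent single-colour (Cy3) whole rat genome array, and a table of values with a column per sample. Per the file headers, the scanner files hold intensity made with Agilent Feature Extraction 12.0.3.1, that is a processed signal in which the background was subtracted and spatial trends were removed, with substitute values for dim spots and no normalization between arrays. The same files hold the mean brightness of each spot and the median brightness around it, also as intensity per the file headers. Other columns are, per the file headers, flags of 0 or 1 for spots that are well above background, saturated or uneven. The deposited value table is in log2 units, and its scale was worked out from the values. Its columns matched the log2 processed signal minus the array's 75th percentile, minus the probe's median over the 16 arrays, averaged over the 4 arrays of a sample, with r of at least 0.99996 across 21030 probes well above background on every array. No unit in the table was contradicted by the scanner files.

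The analysis used the scanner files, since they hold each array apart. Control spots and the 74 to 141 spots per array that the scanner software marked as uneven were left out, and no probe was saturated. The log2 processed signal minus the 75th percentile of the array was taken for 43379 spots, and spots of a probe were averaged, giving 41012 probes. Probes well above background on all 4 arrays of at least 1 group were kept, which left 24039. For each gene the probe with the highest mean over the 16 arrays was used, giving 19498 genes, of which 3483 had several passing probes and 9150 carry a predicted or unnamed locus name. Symbols were brought up to date through RefSeq accessions for 18971 probes, of which 2323 changed, and 22041 probes kept the name given in the files. Probe positions are those of the files, on the rn4 assembly. For arrays, the depth is the signal over background, given per group with the results.

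Genes were tested with limma 3.58.1 in R 4.3.3 (with version 1.17.8 of the data.table package), with 1 mean per group over all 16 arrays, the default moderated test, 2-sided p-values and Benjamini-Hochberg adjustment over genes within a comparison. Array numbers, which come from the names of the files and not from the labels, were not taken to pair the arrays, since this asked for a correlation of deviations over 0.1 in every pair and 5 of the 24 same-number pairs of different groups reached it (range -0.0113 to 0.162, mean 0.0522, against -0.0172 for different numbers). For 10 of the 16 arrays the best match in another group had the same number, so a weak relation is not excluded. An adjusted p under 0.05 was called past the threshold, and the number of genes that also changed at least 2-fold was counted beside it. The comparisons were each fibre against vehicle, each pair of fibres, and an F test for any difference among the 4 groups. No p-value covers the choice among the 6 comparisons. Where a probe was well above background on no array of the lower group, the fold was computed against the lowest signal called well above background on each of those arrays and is given as a lower bound.

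The 25 gene lists covered cytokines and chemokines, NF-kB feedback and targets, interferon-stimulated genes, NRF2 antioxidant response, heat shock and metallothionein, unfolded protein and integrated stress response, lysosome and autophagy, cholesterol biosynthesis and uptake, cholesterol efflux and lipid handling, scavenger and phagocytic receptors, inflammasome and pyroptosis, proteases and matrix remodelling, alternative activation, hypoxia and glycolysis, aryl hydrocarbon receptor targets, cell cycle and DNA replication, p53 and DNA damage, immediate early and AP-1, antigen presentation, iron and ferroptosis, oxidative phosphorylation, alveolar macrophage identity, other lung cell types, other blood cell types, and common reference genes. Each was tested with limma's camera at its preset correlation of 0.01, adjusted over the 25 lists within a comparison, on the 19440 genes with a value on every array. Camera with an estimated correlation and fry were run beside it. At the adjusted p threshold fry, which asks whether the members move one way and compares them with no other genes, called 22, 18 and 21 lists for SCF1, SCF2 and SCF3 against vehicle and 18, 21 and 23 for SCF1 against SCF2, SCF1 against SCF3 and SCF2 against SCF3. Some genes stand in 2 or more lists.

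The groups, comparisons, tests, gene lists, the alternatives unless said otherwise, and the rule for naming genes were fixed before the data were examined. The rule named the 10 genes with the largest rise and fall by the fitted log2 difference for each fibre against vehicle, and the 5 with the largest difference each way for each pair of fibres, among genes with an established name, past the threshold, with arrays of the 2 groups that did not overlap and a probe well above background on every array of the higher group. It also named up to 4 members of each list with the smallest p and any member needed to describe the list, and 17 genes of general interest, of which 16 passed the filter. Of the genes picked in these ways, 2 are not reported here and were left out of the check for arrays far from their group.

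The alternatives were a normexp background with offset 50 and quantile normalization, quantile normalization alone, the array median in place of the 75th percentile, no filter and a stricter filter on dim probes, the mean over the probes of a gene and every probe on its own, a trended robust prior, only the 2 groups compared, array weights, the array number as a block, other thresholds, the value table, and leaving out each array in turn. The method was tested on simulated data drawn from the genes' means and spreads with no group difference, in which 50 genes each were changed 1.25-, 1.5-, 2- and 4-fold in SCF1. The test recovered 40%, 82%, 96% and 98% of them and called 6 unchanged genes in SCF1 against vehicle and 0 to 9 in the other 5 comparisons. Far fewer genes were changed in the simulation than passed the threshold in the data. The adjustment depends on that share, so these rates and counts do not carry over to the real comparisons. In a second draw with 1 list moved, camera called that list and 0 others. Each gene was drawn independently of the others, so this cannot show how often camera calls lists whose members vary together.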

Results

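Gene expression was measured in NR8383 cells, a macrophage cell line derived from rat lung, kept for 24 h with vehicle alone or with 1 of 3 kinds of submicron carbon fibres at 10 µg/mL. The fibres carry the code names SCF1, SCF2 and SCF3. The series set out to evaluate what the fibres do to transcription in these cells. Each of the 4 groups was read on 4 single-colour whole-genome rat arrays, 16 in all, and 19498 genes passed the filter on dim probes. The labels call the 4 arrays of a group replicates and do not say whether they come from separate cultures, so the p-values measure only the spread between these arrays. All 4 arrays of a group lay on 1 slide and each slide held 1 group, so slide and treatment cannot be told apart in any comparison here. The number of arrays limits the precision.

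The 75th percentile of the signal was 459 ± 14.8 (SD, n = 4) in vehicle, 487 ± 12.2 in SCF1, 494 ± 27.9 in SCF2 and 414 ± 60.7 in SCF3, where arrays 3 and 4 were dimmest at 378.1 and 348.5. Probes well above background numbered 24470 to 25648 on the vehicle arrays, 22968 to 23733 on the SCF1 arrays, 23156 to 24381 on the SCF2 arrays and 22271 to 23738 on the SCF3 arrays. The mean signal of the negative control spots was 46.7 ± 0.436 in vehicle against 58.0 ± 2.19 in SCF1, 56.9 ± 1.96 in SCF2 and 56.9 ± 2.02 in SCF3. Arrays of a group correlated across genes with a mean r of 0.996 in vehicle, 0.996 in SCF1, 0.996 in SCF2 and 0.995 in SCF3, and vehicle correlated with the 3 fibre groups at 0.990, 0.994 and 0.975. Genes are not independent replicates, so these r values carry no p.

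The first principal component held 57.4% of the variance and placed vehicle at a mean of -37.2, SCF2 at -24.7, SCF1 at 7.79 and SCF3 at 54.2. The second held 9.39%. Among the 19498 genes, 13638 differed in some way between the 4 groups by the F test.

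**Figure D1:**
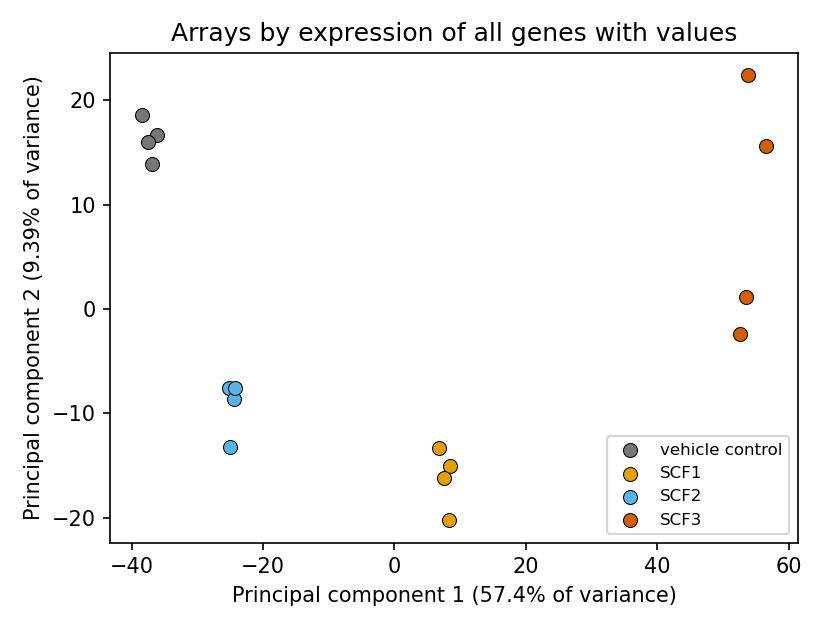
Principal components of the 16 arrays, with component 1 (57.4% of the variance) on the horizontal axis and component 2 (9.39%) on the vertical axis, and 1 point per array coloured by group. The 4 arrays of each group lie together on component 1, and on component 2 the SCF3 arrays spread from -2.43 to 22.4, with arrays 3 and 4 apart from 1 and 2. The group means on component 1 are -37.2 for vehicle, -24.7 for SCF2, 7.79 for SCF1 and 54.2 for SCF3.

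Changes are given as log2 differences between group means with the standard error of the limma fit, over 4 arrays against 4, and negative values are falls. The largest changes are ranked by this difference. For a gene at background in the lower group it rests on values at the floor. Only the bound of its fold is then supported and not its rank, and genes outside the 10 can have larger supported folds. The bounds hold for the main processing alone. Most of the largest changes given as bounds fell short of them with a normexp background and quantile normalization. The naming rule took as largest changes only genes for which the 4 arrays of one group all lay on one side of the 4 arrays of the other. Gene positions are on the rn4 assembly, and no annotation of exons or untranslated regions was at hand for it.

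SCF1 was compared with vehicle to ask which transcripts moved with this fibre. Cells with SCF1 had more RNA for arginase 1 (Arg1, chromosome 1, 21011150 to 21011209), the enzyme that turns arginine into ornithine and urea, which rose by 1.96 ± 0.045, or 3.9-fold (adjusted p = 6.36e-13). The fatty acid binding protein Fabp4 (chromosome 2, 93536175 to 93538589) rose by 2.12 ± 0.039, or 4.36-fold, and the macrophage elastase Mmp12 (chromosome 8, 4259057 to 4259413) by 1.41 ± 0.14. Most genes of the cell cycle and DNA replication list fell, among them cyclin B2 (Ccnb2, chromosome 8, 74896165 to 74896224) at -1.05 ± 0.057 and the spindle checkpoint kinase Bub1 (chromosome 3, 115324635 to 115324694) at -0.8 ± 0.04.

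Of 19498 genes, 8330 (42.7%) passed the threshold in SCF1 against vehicle, 3979 higher and 4351 lower, with a median absolute change of 0.35 among them. A fold change of at least 2 as well was met by 542 genes, 277 higher and 265 lower. The 4 SCF1 arrays and the 4 vehicle arrays did not overlap for 8559 of the 19498 genes, where chance separates 2.86% of genes.

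By the fitted difference, the 10 named genes with the largest rise in SCF1 began with the sodium bicarbonate transporter Slc4a8 (chromosome 7, 139572855 to 139574186), which rose by 5.03 ± 0.23. It was well above background on no vehicle array, so the fold is a lower bound of at least 9.9-fold. The dopamine transporter Slc6a3 rose by 4.44, a value that rests partly on the floor, since most vehicle arrays were not well above background for it. The actin-binding protein Xirp1 (chromosome 8, 124996302 to 124996361) rose by 3.66 ± 0.078, or 12.6-fold, and suprabasin (Sbsn, chromosome 1, 85796499 to 85796558) by 3.48 ± 0.073, or 11.1-fold. The keratin Krt76 was at least 4.65-fold higher, the matrix protein fibulin 1 (Fbln1) at least 2.48-fold and the diacylglycerol kinase Dgkg at least 6.57-fold. Doublecortin (Dcx) rose by 3.09, the actin regulator Eps8 by 2.79 and natriuretic peptide B (Nppb) by 2.68. Of the 10 largest fitted falls, 9 were of genes well above background on no SCF1 array, so their folds are lower bounds. Hnrnpll, a splicing regulator, was at least 4.33-fold lower and Plagl1, a zinc finger transcription factor, at least 2.1-fold lower. The odorant receptors Or1j22 and Or10s1 were at least 3.18-fold and 2.85-fold lower. Epb41l4a was at least 2.07-fold lower, Olfml2a at least 1.74-fold, Ttpa at least 1.72-fold and the keratin Krt73 at least 1.71-fold. Ypel2 fell (-2.08) on its brightest probe and lay at -1.06 as the mean of its 2 probes. With a normexp background and quantile normalization, 17 of these 20 changes moved by over 1.5 times, and all kept their direction and their side of the threshold. Each of these changes given as a bound then fell short of it, for example Slc4a8 at 1.33, Krt76 at 0.731, Fbln1 at 0.433, Dgkg at 0.899 and Hnrnpll at -0.868. Slc6a3, Dcx and Nppb, given without a bound, then lay at 1.59, 1.67 and 0.943. Only 5 of the 20 genes had a probe well above background on every array.

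The clearest list was cell cycle and DNA replication. In SCF1, 0 of 37 members were higher, 34 lower and 3 did not pass (0 higher and 34 lower adjusted over the list alone), with a median of -0.57 (camera adjusted p = 5.58e-20). The proliferation marker Mki67 fell (-0.4), the mitotic regulators Ccnb1 and Nusap1 (-0.69 and -0.95), the transcription factor E2f1 (-0.57) and the ribonucleotide reductase subunit Rrm2 (-0.8).

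Most genes of the lysosome and autophagy list rose in SCF1. Here 24 of 33 members were higher, 1 lower and 8 did not pass (25 higher and 1 lower adjusted over the list alone), with a median of 0.26 (adjusted p = 5.79e-10). The lysosomal sialidase Neu1 rose by 0.56, the galactosidase Gla by 0.87, the autophagy receptor Sqstm1 (chromosome 10, 35751726 to 35751785) by 0.81 and Gabarapl1, which acts in autophagosome formation, by 0.73. In the unfolded protein and integrated stress response list, 18 of 26 members were higher, 0 lower and 8 did not pass (19 higher and 0 lower adjusted over the list alone), with a median of 0.32 (adjusted p = 1.7e-07). The stress transcription factor Atf3 rose by 1.09, the pseudokinase Trib3 (chromosome 3, 142664064 to 142664123) by 0.8, the phosphatase subunit Ppp1r15a by 0.78 and the transcription factor Ddit3 by 0.69. Of the hypoxia and glycolysis list, 19 of 30 members were higher, 2 lower and 9 did not pass (19 higher and 3 lower adjusted over the list alone), with a median of 0.25 (adjusted p = 1.72e-06). The lactate exporter Slc16a3 rose by 1.25, the glucose transporter Slc2a1 by 0.67 and hexokinase 2 (Hk2) by 1.01, and hexokinase 1 (Hk1) was at least 3.99-fold higher. In proteases and matrix remodelling, 14 of 23 members were higher, 1 lower and 8 did not pass (14 higher and 1 lower adjusted over the list alone), with a median of 0.32, or 0.25 with the 1 member at background in the lower group set to its bound (adjusted p = 0.000559). The matrix metalloproteinases Mmp10, Mmp9 and Mmp2 rose by 1.56, 1.18 and 0.81, and the urokinase receptor Plaur by 0.85. All 5 of these lists, cell cycle included, stayed past the threshold with an estimated correlation, with adjusted p of 0.00271, 0.00271, 0.0103, 0.0244 and 0.0424 in the order given.

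In the NF-kB feedback and targets list, 14 of 17 members were higher, 1 lower and 2 did not pass (14 higher and 2 lower adjusted over the list alone), with a median of 0.44 (adjusted p = 7.35e-07, or adjusted p = 0.0754 with an estimated correlation). Inducible nitric oxide synthase (Nos2) rose by 1.65, the adhesion molecule Icam1 by 0.82, the apoptosis inhibitor Birc3 by 1.05 and the NF-kB inhibitor Nfkbib by 0.78. Of the NRF2 antioxidant response, 11 of 25 members were higher, 3 lower and 11 did not pass (11 higher and 3 lower adjusted over the list alone) (median 0.16, adjusted p = 0.0334, or adjusted p = 0.169 with an estimated correlation). Heme oxygenase 1 (Hmox1) rose by 0.53, thioredoxin reductase 1 (Txnrd1) by 0.49 and sulfiredoxin (Srxn1) by 0.71. The quinone reductase Nqo1 was 0.16 higher (adjusted p = 0.0222), a call that ended without vehicle replicate 3 or SCF1 replicate 4 (adjusted p up to 0.0667). The glutathione synthesis subunit Gclm was at least 1.25-fold lower, a call that ended without vehicle replicate 2 or SCF1 replicate 3 (adjusted p up to 0.0659). Of cholesterol biosynthesis and uptake, 11 of 25 members were higher, 3 lower and 11 did not pass (11 higher and 3 lower adjusted over the list alone) (median 0.08, adjusted p = 0.0334, or adjusted p = 0.169 with an estimated correlation), a call that ended without vehicle replicate 4 or SCF1 replicate 4 (adjusted p up to 0.0612). Insig1 and Fdps, both of sterol metabolism, rose by 0.4 and 0.39, and the sterol reductase Tm7sf2 fell (-0.4). Of p53 and DNA damage, 9 of 19 members were higher, 4 lower and 6 did not pass (9 higher and 4 lower adjusted over the list alone) (median 0.12, adjusted p = 0.0334, or adjusted p = 0.0724 with an estimated correlation). The stress sensors Gadd45b and Gadd45a rose by 1.38 and 0.62, and the cyclin kinase inhibitor Cdkn1a by 0.16. The calls of the NRF2 and cholesterol biosynthesis lists ended with quantile normalization (adjusted p = 0.129 and 0.086), that of NRF2 also with a normexp background and quantile normalization (adjusted p = 0.134) and that of cholesterol biosynthesis with the array median (adjusted p = 0.0504). With probes well above background on all arrays the calls of cholesterol biosynthesis and p53 ended (adjusted p = 0.0761 and 0.0721).

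Against other genes, cytokines and chemokines were not past the threshold as a list in SCF1 (adjusted p = 0.124), whereas fry, which looks at the members alone, called them (adjusted p = 2.31e-05). Here 7 of 20 members were higher, 3 lower and 10 did not pass (7 higher and 3 lower adjusted over the list alone). The chemokines Ccl4, Ccl9 and Ccl3 rose by 1.43, 1.23 and 0.53 and Tnf by 0.78, and interleukin 1 beta (Il1b) fell (-0.23). Il6, Ccl2 and Cxcl2 did not pass, with changes of -0.01, -0.12 and 0.09. Osteopontin (Spp1) rose by 0.41, and the inflammasome sensor Nlrp3 fell (-0.43). In alternative activation, 5 of 16 members were higher, 3 lower and 8 did not pass (5 higher and 3 lower adjusted over the list alone) (adjusted p = 0.0525), and the call was gained with the array median (adjusted p = 0.0437). Beside Arg1, the interleukin 1 receptor antagonist Il1rn rose by 1.52 and transglutaminase 2 (Tgm2) by 1.5. The reference genes Actb and Gapdh were 0.2 and 0.26 higher, and Actb lay at -0.00324 with a normexp background and quantile normalization. Among markers of other lung cell types, more fell than rose past the threshold. The fibroblast gene decorin (Dcn) rose by 0.82, and the epithelial keratin Krt18 was not past the threshold at 0.33.

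SCF2 was compared with vehicle for the same purpose. The changes were smaller, with a median absolute change of 0.31 among the genes past the threshold. Arg1 rose by 0.32 ± 0.045, or 1.25-fold (adjusted p = 0.000668), Fabp4 by 0.53 ± 0.039, or 1.44-fold, and the matrix metalloproteinases Mmp10 and Mmp9 by 0.6 and 0.57. The inflammatory genes Nos2, Osm and Ccl3 rose by 0.51, 0.48 and 0.45, and the stress transcription factors Ddit3, Atf3 and Atf4 by 0.4, 0.43 and 0.46. Mmp12 did not pass, at -0.14 ± 0.14 (adjusted p = 0.525), and lay at 0.055 without SCF2 replicate 3.

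Of 19498 genes, 2479 (12.7%) passed the threshold in SCF2, 1352 higher and 1127 lower, and 146 of them had a fold change of at least 2, 72 higher and 74 lower. The arrays of the 2 groups did not overlap for 4276 of the 19498 genes (2.86% by chance). Without vehicle replicate 2 the number of genes past the threshold was 1613.

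By the same ranking, the 10 named genes with the largest rise in SCF2 began with the ryanodine receptor Ryr3 (chromosome 3, 98714987 to 98715046), a calcium channel, which was at least 3.02-fold higher. The calcium channel subunit Cacng3 rose by 1.6 ± 0.16, ladinin (Lad1) by 1.51, the gasdermin Gsdma by 1.42, Efs by 1.39, Zfp474 by 1.37, the receptor kinase Erbb2 by 1.25, the adenylate kinase Ak9 by 1.23 and Sbsn by 1.21 ± 0.073. Sprtn rose by 1.29 ± 0.39 (adjusted p = 0.0452), a call lost in 11 of the 16 fits that left out 1 array, namely vehicle replicates 2 and 3, SCF1 replicates 1, 3 and 4, SCF2 replicates 1 to 4 and SCF3 replicates 2 and 3 (adjusted p up to 0.106). Without vehicle replicate 3 the change of Sprtn was 0.80, with an adjusted p of 0.0666. Among the 10 largest fitted falls, Hnrnpll fell (-2.57), Plagl1 was at least 2.04-fold lower, Olfml2a at least 1.7-fold, the peroxisomal enzyme Phyh at least 1.37-fold and Purg at least 2.45-fold. The planar polarity protein Vangl1 fell (-1.97), Dlk1 (-1.81), the interferon Ifna4 (-1.8) and the chemokine Ccl11 (-1.72). Cyp11b3 fell, at -1.46 ± 0.4 (adjusted p = 0.0295), a call that ended without vehicle replicate 2, 3 or 4 or SCF2 replicate 2, 3 or 4 (adjusted p up to 0.0794). With a normexp background and quantile normalization, 19 of these 20 changes moved by over 1.5 times and the call of Sprtn ended. Each of these changes given as a bound then fell short of it, for example Ryr3 at 0.461 and Purg at -0.367. With only the 2 groups compared in the fit, 1 of the 20 calls ended.

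In the unfolded protein and integrated stress response list, 8 of 26 members were higher, 1 lower and 17 did not pass (11 higher and 1 lower adjusted over the list alone) in SCF2 (median 0.14, adjusted p = 0.00013, or adjusted p = 0.0646 with an estimated correlation). Trib3 rose by 0.27 and Ppp1r15a by 0.22. Of cytokines and chemokines, 6 of 20 members were higher, 0 lower and 14 did not pass (7 higher and 0 lower adjusted over the list alone) (median 0.19, adjusted p = 0.000296, or adjusted p = 0.114 with an estimated correlation). Interleukin 1 alpha (Il1a) rose by 0.29, Ccl4 by 0.26 and Ccl9 by 0.27, whereas Tnf, Ccl2, Il6, Il1b and Cxcl2 did not pass, at 0.2, 0.34, 0.19, -0.05 and 0.16. Of lysosome and autophagy genes, 8 of 33 members were higher, 2 lower and 23 did not pass (11 higher and 2 lower adjusted over the list alone) (median 0.08, adjusted p = 0.000509, or adjusted p = 0.0667 with an estimated correlation). The lysosomal proteases Lgmn and Ctsd rose by 0.39 and 0.34 and Neu1 by 0.22. Of alternative activation, 6 of 16 members were higher, 0 lower and 10 did not pass (7 higher and 0 lower adjusted over the list alone) (median 0.12, adjusted p = 0.000944), and this list alone stayed past the threshold with an estimated correlation (adjusted p = 0.0392). The chemokine Ccl17 rose by 0.44 and Tgm2 by 0.39.

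Of hypoxia and glycolysis, 4 of 30 members were higher, 0 lower and 26 did not pass (7 higher and 1 lower adjusted over the list alone) in SCF2 (median 0.11, adjusted p = 0.00212, or adjusted p = 0.124 with an estimated correlation), among them Slc16a3 at 0.33, Slc2a1 at 0.21 and Hk1, at least 1.2-fold higher. Of proteases and matrix remodelling, 5 of 23 members were higher, 0 lower and 18 did not pass (5 higher and 0 lower adjusted over the list alone) (median 0.07, or 0.0664 with the 1 member at background in the lower group set to its bound, adjusted p = 0.0204, or adjusted p = 0.16 with an estimated correlation), with Plaur at 0.44. Of iron and ferroptosis, 4 of 19 members were higher, 1 lower and 14 did not pass (6 higher and 2 lower adjusted over the list alone) (median 0.13, adjusted p = 0.0204, or adjusted p = 0.0688 with an estimated correlation), and the metal transporter Slc11a1 rose by 0.22. Of immediate early and AP-1 genes, 6 of 22 members were higher, 2 lower and 14 did not pass (7 higher and 2 lower adjusted over the list alone) (median 0.06, adjusted p = 0.0437, or adjusted p = 0.209 with an estimated correlation), a call that ended without vehicle replicate 1, 2 or 3, SCF2 replicate 2 or 3 or SCF3 replicate 2 (adjusted p up to 0.0671). Of cell cycle and DNA replication, 1 of 37 members were higher, 8 lower and 28 did not pass (1 higher and 9 lower adjusted over the list alone) (median -0.04, adjusted p = 0.0204, or adjusted p = 0.256 with an estimated correlation), a call that ended without vehicle replicate 3 (adjusted p = 0.0503). Ccnb2 fell (-0.24), Bub1 (-0.18), Rrm2 (-0.24), E2f1 (-0.21) and the helicase loader Cdc6 (-0.25). Mki67 rose by 0.26 (adjusted p = 0.0232), a call that ended without vehicle replicate 3 or 4 or SCF2 replicate 4 (adjusted p up to 0.0654). The calls of hypoxia and glycolysis, proteases and immediate early genes ended with quantile normalization (adjusted p = 0.0578, 0.0571 and 0.0632), and those of hypoxia and glycolysis and of iron and ferroptosis with a normexp background and quantile normalization (adjusted p = 0.344 and 0.0523). That of immediate early genes also ended with the array median (adjusted p = 0.062) and with probes well above background on all arrays (adjusted p = 0.0606).

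Hmox1, Nqo1, Gclm, Nlrp3, Spp1, Cdkn1a and Actb did not pass in SCF2, with changes of 0.04, -0.14, 0.03, 0.15, -0.06, 0.02 and 0.06. No marker of other lung cell types passed, and Dcn and Krt18 lay at 0.15 and 0.41.

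SCF3 was compared with vehicle for the same purpose and gave the most genes past the threshold of the 3 fibres. Arg1 rose by 3.65 ± 0.045, or 12.6-fold (adjusted p = 2.21e-16), Fabp4 by 3.4 ± 0.039, or 10.5-fold, and Mmp12 by 2.5 ± 0.14. The activin subunit Inhba (chromosome 17, 57240473 to 57240532) rose by 5.02 ± 0.085, or 32.4-fold, on all 3 of its probes. The succinate receptor Sucnr1 (chromosome 2, 149416392 to 149416451) was at least 5.84-fold lower, Ccnb2 fell (-1.99 ± 0.057) and Bub1 (-1.63 ± 0.04).

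Of 19498 genes, 12455 (63.9%) passed the threshold in SCF3, 6207 higher and 6248 lower, with a median absolute change of 0.48. A fold change of at least 2 as well was met by 1895 genes, 906 higher and 989 lower. The arrays of the 2 groups did not overlap for 10680 of the 19498 genes (2.86% by chance). With the dimmer SCF3 arrays 3 and 4 left out, a choice made after seeing the data, 11947 genes passed and 1992 of them changed at least 2-fold.

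The 10 named genes with the largest fitted rise in SCF3 shared 7 with those of SCF1. Slc4a8 was at least 64.2-fold higher, Fbln1 at least 13.5-fold, the fatty acid binding protein Fabp9 at least 24.6-fold and Krt76 at least 13.5-fold. Slc6a3, well above background on 1 vehicle array, rose by 6.81, Xirp1 by 6.07 ± 0.078, or 67.1-fold, Nppb by 5.45, Sbsn by 5.19 ± 0.073, or 36.4-fold, and Gsg1 by 5.17. Among the largest fitted falls beside Sucnr1, Hnrnpll was at least 3.57-fold lower and the endothelial regulator Apold1 at least 2.2-fold. Afdn, an adaptor of cell junctions, fell (-2.36 ± 0.094), as did the liver glycogen synthase Gys2 (-2.35), the transcription factor Tshz1 (-2.34), Arhgef39 (-2.32), the MAX partner Mxd3 (-2.31), Lypd8l1 (-2.23) and the mitotic kinesin Kif14 (-2.22). With a normexp background and quantile normalization, 13 of these 20 changes moved by over 1.5 times, and all kept their direction and their side of the threshold. Each of these changes given as a bound then fell short of it, for example Slc4a8 at 3.42, Fbln1 at 1.48, Fabp9 at 2.05 and Sucnr1 at -1.06. Slc6a3, given without a bound, then lay at 3.54.

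Every measured member of the cell cycle and DNA replication list was lower in SCF3. Here 0 of 37 members were higher, 37 lower and 0 did not pass (0 higher and 37 lower adjusted over the list alone), with a median of -1.26 (adjusted p = 6.27e-19). Mki67 fell (-1.26), Bub1b (-1.9), Nusap1 (-1.99), Ccnb1 (-1.45), Rrm2 (-1.55), E2f1 (-1.35) and Cdc6 (-1.17). Of lysosome and autophagy genes, 27 of 33 members were higher, 3 lower and 3 did not pass (27 higher and 3 lower adjusted over the list alone), with a median of 0.53 (adjusted p = 5.41e-07). Sqstm1 rose by 1.73 ± 0.061, Gla by 1.5, Gabarapl1 by 1.3 and Neu1 by 0.92. Of the unfolded protein and integrated stress response, 18 of 26 members were higher, 2 lower and 6 did not pass (19 higher and 2 lower adjusted over the list alone), with a median of 0.41 (adjusted p = 2.84e-05). Trib3 rose by 2.18 ± 0.05, Atf3 by 2.5, Ddit3 by 1.95, Ppp1r15a by 1.92 and Atf4 by 1.43. These 3 lists stayed past the threshold with an estimated correlation, with adjusted p of 0.00349, 0.0121 and 0.0382.

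Of hypoxia and glycolysis, 23 of 30 members were higher, 5 lower and 2 did not pass (24 higher and 5 lower adjusted over the list alone) in SCF3 (median 0.50, adjusted p = 6.69e-05, or adjusted p = 0.0513 with an estimated correlation). Slc16a3, Slc2a1 and Hk2 rose by 1.56, 1.25 and 1.24, and Hk1 was at least 17.2-fold higher. Of proteases and matrix remodelling, 16 of 23 members were higher, 4 lower and 3 did not pass (16 higher and 4 lower adjusted over the list alone) (median 0.56, adjusted p = 0.0014, or adjusted p = 0.0513 with an estimated correlation). Mmp10, Mmp2 and Mmp9 rose by 2.68, 2.55 and 0.93, and Spp1 rose by 0.53. Of NF-kB feedback and targets, 11 of 17 members were higher, 3 lower and 3 did not pass (11 higher and 3 lower adjusted over the list alone) (median 0.57, adjusted p = 0.00359, or adjusted p = 0.275 with an estimated correlation), with Icam1 at 1.54, Birc3 at 1.74, Nfkbib at 1.49 and Nos2 at 1.42. Of p53 and DNA damage, 12 of 19 members were higher, 3 lower and 4 did not pass (12 higher and 4 lower adjusted over the list alone) (median 0.26, adjusted p = 0.0222, or adjusted p = 0.0513 with an estimated correlation). Gadd45b rose by 3.56 ± 0.05, Gadd45a by 2.38 and Cdkn1a by 0.7. Of immediate early and AP-1 genes, 14 of 22 members were higher, 7 lower and 1 did not pass (14 higher and 7 lower adjusted over the list alone) (median 0.45, adjusted p = 0.0222, or adjusted p = 0.159 with an estimated correlation), with the small Maf protein Maff at 2.92. The call of the immediate early list ended with probes well above background on all arrays (adjusted p = 0.0693).

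Against other genes, cytokines and chemokines were not past the threshold as a list in SCF3 (adjusted p = 0.0802), whereas fry called them (adjusted p = 3.23e-09). Here 9 of 20 members were higher, 5 lower and 6 did not pass (9 higher and 5 lower adjusted over the list alone). Ccl4 rose by 2.94, Osm by 1.81, Tnf by 1.31, Ccl2 by 1.07 and Ccl3 by 1.02, Il1b fell (-0.19), and Il6 and Cxcl2 did not pass at -0.1 and 0.08. In alternative activation, 10 of 16 members were higher, 4 lower and 2 did not pass (10 higher and 4 lower adjusted over the list alone) (adjusted p = 0.0533, gained with quantile normalization at adjusted p = 0.048 and with a normexp background and quantile normalization at adjusted p = 0.0483), with Il1rn at 2.31, Tgm2 at 2.11 and Ccl17 at 0.79. In the NRF2 antioxidant response, 11 of 25 members were higher, 7 lower and 7 did not pass (11 higher and 7 lower adjusted over the list alone) (adjusted p = 0.334). Hmox1 rose by 1.07, Srxn1 by 1.38, Txnrd1 by 1.0 and Nqo1 by 0.27, and Gclm was at least 1.04-fold lower. Nlrp3 fell (-0.9), and Actb and Gapdh rose by 0.46 and 0.44. Among markers of other lung cell types, Krt18 rose by 2.01 and Dcn by 1.04.

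**Figure D2:**
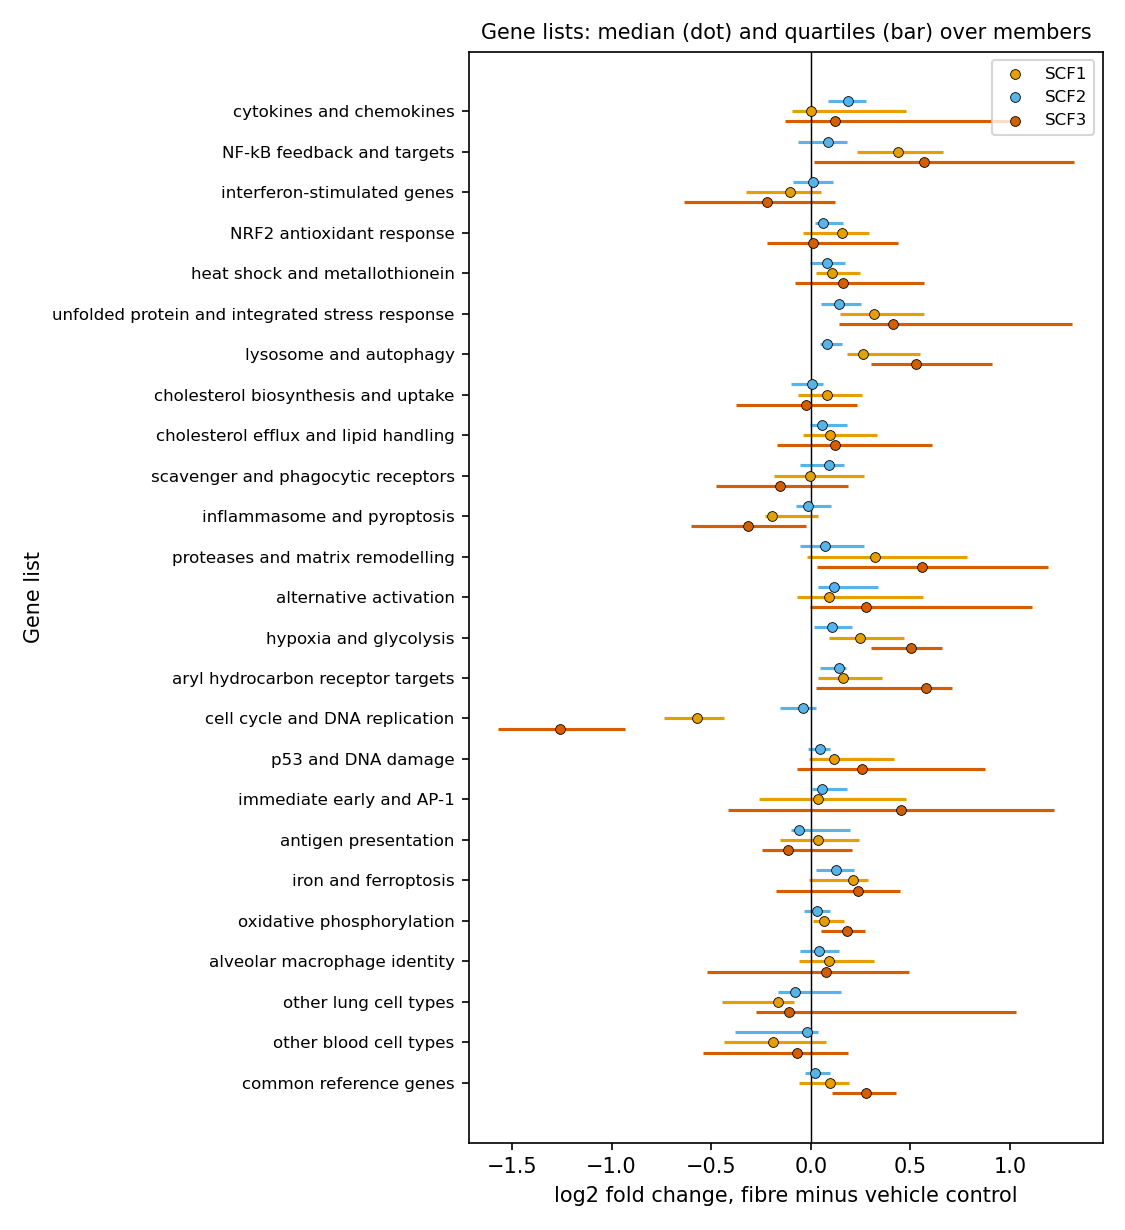
Log2 change against vehicle of the 25 gene lists in SCF1, SCF2 and SCF3, with the median of the measured members as a dot and the quartiles as a bar. Cell cycle and DNA replication had the lowest median in SCF1 and SCF3, at -0.57 and -1.26, and lay at -0.04 in SCF2.

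**Figure D3:**
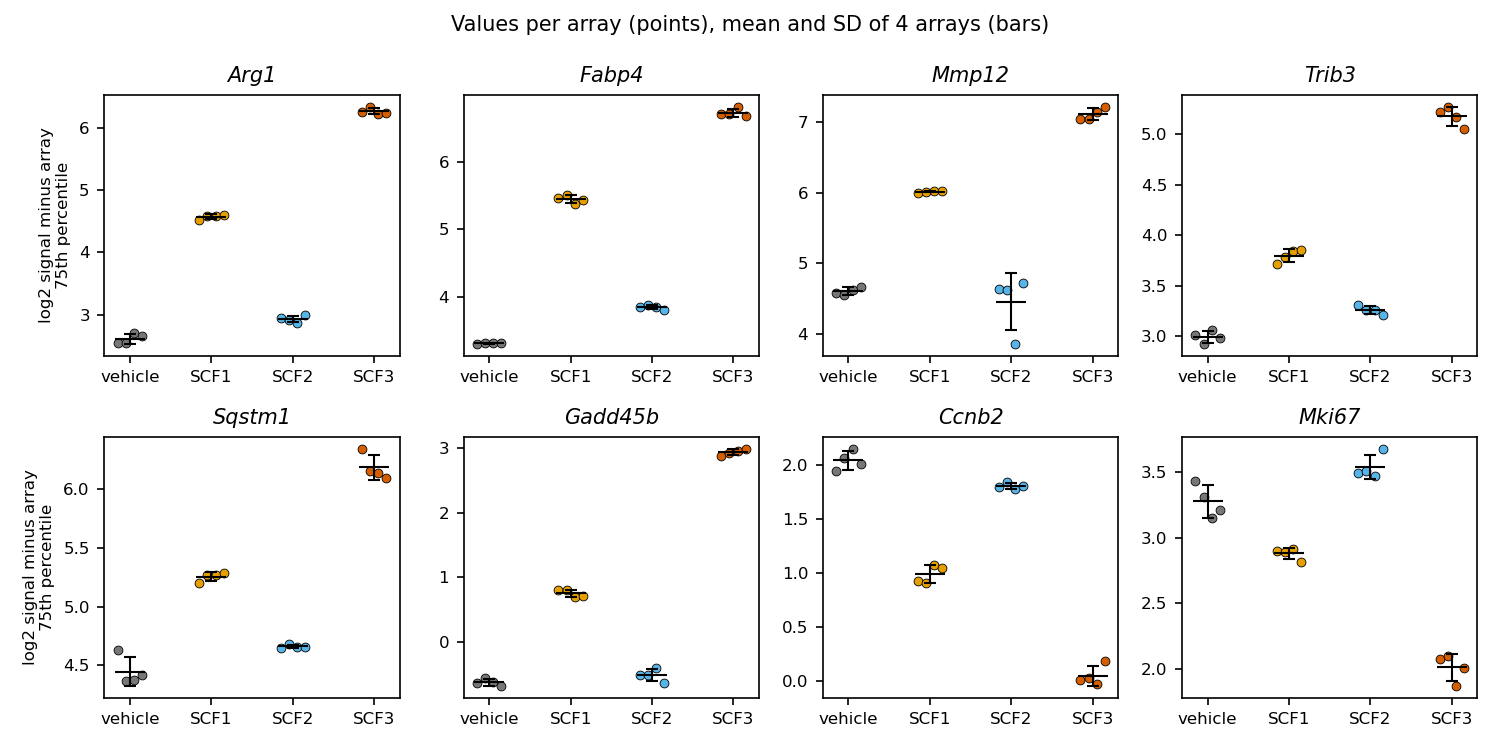
Log2 signal minus the array's 75th percentile for Arg1, Fabp4, Mmp12, Trib3, Sqstm1, Gadd45b, Ccnb2 and Mki67, with 1 point per array and the mean and SD of the 4 arrays of each group. Arg1 rose by 1.96, 0.32 and 3.65 against vehicle in SCF1, SCF2 and SCF3, and Ccnb2 fell (-1.05, -0.24 and -1.99).

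Against other genes, the remaining lists were not past the threshold as lists in any fibre group, although single members were. Of heat shock and metallothionein genes, 6 of 17 were higher and 1 lower in SCF1, 2 and 0 in SCF2 and 7 and 2 in SCF3 (adjusted p = 0.0525, 0.0564 and 0.0931), the same counts as adjusted over the list alone. The small heat shock protein Hspb1 rose by 1.64, 0.25 and 2.91. Of aryl hydrocarbon receptor targets, 4, 1 and 5 of 7 were higher and 0, 0 and 2 lower (4, 3 and 5 higher and 1, 1 and 2 lower adjusted over the list alone), with adjusted p of 0.125, 0.153 and 0.197, and Tiparp rose by 0.36, 0.25 and 0.76. Cyp1b1 was on the array but did not pass the filter on dim probes. Of cholesterol efflux and lipid handling, 8, 4 and 11 of 22 were higher and 4, 2 and 7 lower (8, 5 and 11 higher and 5, 3 and 7 lower adjusted over the list alone), with adjusted p of 0.104, 0.0902 and 0.464. The LXR target Mylip fell (-0.94, -0.49 and -1.69), and the lipid droplet protein Plin2 rose by 0.61 in SCF1 and 1.52 in SCF3.

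Of interferon-stimulated genes, 4, 1 and 6 of 26 were higher and 7, 1 and 13 lower in SCF1, SCF2 and SCF3 (7, 1 and 14 lower adjusted over the list alone), with adjusted p of 0.43, 0.804 and 0.331. The protease Usp18 rose by 0.9, 0.33 and 1.4, whereas the GTPase Ifi47 fell in SCF1 and SCF3 (-0.57 and -1.24). Of inflammasome and pyroptosis genes, 8, 2 and 8 of 14 were lower and 2, 2 and 3 higher (8, 3 and 8 lower and 2, 3 and 3 higher adjusted over the list alone), with adjusted p of 0.128, 0.802 and 0.0598. The call in SCF3 was gained with quantile normalization (adjusted p = 0.0349) and with a normexp background and quantile normalization (adjusted p = 0.0483). Caspase 1 (Casp1) fell in SCF1 and SCF3 (-0.23 and -0.44). Of scavenger and phagocytic receptors, 8, 4 and 7 of 18 were higher and 5, 1 and 10 lower (8, 7 and 7 higher and 7, 2 and 10 lower adjusted over the list alone), with adjusted p of 0.476, 0.098 and 0.331. The scavenger receptor Olr1 rose by 0.73 in SCF1 and 2.14 in SCF3, and the Fc receptor Fcgr1a fell (-0.62, -0.24 and -1.12).

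Of antigen presentation genes, 3, 3 and 3 of 13 were higher and 3, 1 and 5 lower, with the same counts adjusted over the list alone and adjusted p of 0.605, 0.884 and 0.729. RT1-DMa fell in SCF1 and SCF3 (-0.43 and -0.7). Of oxidative phosphorylation genes, 6, 1 and 17 of 29 were higher and 2, 0 and 3 lower, as they were adjusted over the list alone, with adjusted p of 0.117, 0.19 and 0.067. With the array median the calls of oxidative phosphorylation and of heat shock and metallothionein were gained in SCF1 (adjusted p = 0.0436 and 0.0437). Cytochrome c (Cycs) rose by 0.45 in SCF1 and 0.87 in SCF3. Of alveolar macrophage identity genes, 8, 5 and 9 of 19 were higher and 4, 3 and 8 lower (8, 6 and 9 higher adjusted over the list alone), with adjusted p of 0.104, 0.153 and 0.729. The growth factor receptor Csf1r fell in SCF1 and SCF3 (-0.44 and -0.86). Of the common reference genes, 7, 2 and 9 of 15 were higher and 1, 0 and 3 lower (8, 2 and 10 higher and 1, 0 and 3 lower adjusted over the list alone), with adjusted p of 0.0889, 0.153 and 0.0598, and B2m rose by 0.39, 0.31 and 0.57. Of markers of other lung cell types, 1, 0 and 3 of 9 were higher and 3, 0 and 2 lower, as adjusted over the list alone (adjusted p = 0.476, 0.897 and 0.768). Of markers of other blood cell types, 1, 0 and 1 of 7 were higher and 1, 1 and 2 lower (1, 1 and 0 higher and 1, 2 and 0 lower adjusted over the list alone), with adjusted p of 0.739, 0.695 and 0.873.

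For the lists called in some fibre groups alone, the remaining adjusted p were 0.0797 for NF-kB feedback and targets, 0.0797 for the NRF2 antioxidant response, 0.864 for cholesterol biosynthesis and 0.262 for p53 and DNA damage in SCF2. The call of NF-kB feedback and targets in SCF2 was gained with a normexp background and quantile normalization (adjusted p = 0.0454). The remaining adjusted p were 0.195 for immediate early genes and 0.0565 for iron and ferroptosis in SCF1, and 0.896 and 0.438 for cholesterol biosynthesis and iron and ferroptosis in SCF3. The lipoxygenase Alox5, of the iron and ferroptosis list, fell in SCF1 and SCF3 (-0.66 and -1.52). The median, mean and test of a list differed in sign for scavenger and phagocytic receptors in SCF1, for interferon-stimulated genes, cholesterol biosynthesis and antigen presentation in SCF2, and for cholesterol biosynthesis, antigen presentation and other lung cell types in SCF3.

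The 3 fibres were compared with one another at the same dose and time to ask whether the kinds of fibre differed. Arg1 was 1.64 ± 0.045 higher with SCF1 than with SCF2, and its differences for SCF1 minus SCF3 and SCF2 minus SCF3 were -1.69 ± 0.045 and -3.33 ± 0.045. For Fabp4 these were 1.59, -1.27 and -2.87, and for Trib3 0.54, -1.38 and -1.91. Ccnb2 differed in the other direction, with -0.81 for SCF1 minus SCF2, 0.94 for SCF1 minus SCF3 and 1.76 for SCF2 minus SCF3. Between SCF1 and SCF3 there were 9025 genes past the threshold, 4333 higher and 4692 lower with SCF1, and 517 with a fold change of at least 2 (120 and 397). Between SCF1 and SCF2 there were 5766, 2894 higher and 2872 lower with SCF1, and 244 of at least 2-fold (141 and 103). Between SCF2 and SCF3 there were 11554, 5718 higher and 5836 lower with SCF2, and 1419 of at least 2-fold (687 and 732).

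With SCF1 against SCF2, the largest fitted differences upward were those of Slc4a8, at least 6.52-fold, Slc6a3 at 2.95, Fbln1, at least 1.63-fold, Xirp1 at 2.55 and Dcx at 2.46. Downward they were Or1j22, at least 1.82-fold, Rtkn2 at -1.4, Lrtm2 at -1.31, Ergic2 at -1.17 and Or4a47 at -1.09. Rtkn2 lay at -0.85 without SCF2 replicate 3. With a normexp background and quantile normalization 8 of these 10 differences moved by over 1.5 times, and the call of Or4a47 ended at -0.13 (adjusted p = 0.122). Slc6a3 then lay at 1.37. With only the 2 groups compared in the fit, 1 of the 10 calls ended. Among the lists, cell cycle and DNA replication was lower with SCF1 (34 of 37 members lower and 0 higher, 35 lower adjusted over the list alone, adjusted p = 1.5e-24). NF-kB feedback and targets (13 of 17 higher and 0 lower, 14 and 0 adjusted over the list alone, adjusted p = 1.54e-08), lysosome and autophagy (19 of 33 higher and 1 lower, 20 and 1 adjusted over the list alone, adjusted p = 1.54e-08) and the unfolded protein response (12 of 26 higher and 0 lower, 15 and 1 adjusted over the list alone, adjusted p = 1.26e-05) were higher. Hypoxia and glycolysis, cholesterol biosynthesis and proteases were higher as well, with 17 of 30, 10 of 25 and 9 of 23 members higher and 1, 2 and 1 lower (18, 11 and 9 higher and 1, 2 and 1 lower adjusted over the list alone) and adjusted p of 1.72e-05, 0.00526 and 0.0053. With an estimated correlation the adjusted p were 0.00105, 0.0544, 0.00565, 0.0329, 0.0439, 0.0872 and 0.0872 in the order given. The call of p53 was gained with the array median (adjusted p = 0.0312).

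With SCF1 against SCF3, Sucnr1 was at least 2.29-fold higher with SCF1 and Kynu, a kynurenine-cleaving enzyme, at least 1.16-fold, and the chromatin protein Jade2 and Afdn were 1.46 and 1.37 higher. The desaturase Scd2 was 1.6 higher on its brightest probe and 0.38 as the mean over its 3 probes, of which 1 had that sign. Inhba, Fabp9, Gsg1 and Nppb were lower with SCF1, at -2.87, -2.86, -2.79 and -2.77, and the synaptic immediate early gene Arc was at least 2.64-fold lower. With a normexp background and quantile normalization 5 of these 10 differences moved by over 1.5 times. Cell cycle and DNA replication was higher with SCF1 (33 of 37 members higher and 1 lower, 34 and 1 adjusted over the list alone, adjusted p = 1.27e-19, or adjusted p = 0.00297 with an estimated correlation). Lysosome and autophagy, immediate early genes, the unfolded protein response, hypoxia and glycolysis, p53 and proteases were lower with SCF1, with 20, 15, 12, 16, 9 and 13 members lower and 5, 4, 4, 3, 4 and 6 higher (23, 15, 12, 17, 10 and 13 lower and 6, 5, 5, 3, 4 and 6 higher adjusted over the list alone) and adjusted p of 0.00289, 0.0032, 0.00402, 0.0124, 0.0125 and 0.0184. With an estimated correlation these 6 calls were lost (adjusted p = 0.0892, 0.0892, 0.126, 0.15, 0.0892 and 0.142). That of hypoxia and glycolysis also ended with quantile normalization (adjusted p = 0.102) and with a normexp background and quantile normalization (adjusted p = 0.0803). Scavenger receptors, cholesterol biosynthesis and inflammasome genes were higher with SCF1, with 10, 9 and 6 members higher and 1, 3 and 1 lower (the same counts adjusted over the list alone), adjusted p of 0.0122, 0.0184 and 0.0479, and adjusted p of 0.142, 0.15 and 0.205 with an estimated correlation. The inflammasome call ended in 3 of the 16 fits that left out 1 array (adjusted p up to 0.0817), those without SCF1 replicate 3, SCF3 replicate 1 or SCF3 replicate 4, with the array number as a block (adjusted p = 0.0635) and with probes well above background on all arrays (adjusted p = 0.095).

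With SCF2 against SCF3, Sucnr1 was at least 4.42-fold higher with SCF2, and Mxd3, Afdn and Tshz1 were 2.23, 2.21 and 2.2 higher. Spag8 was 2.37 ± 0.84 higher (adjusted p = 0.0253), at 1.11 without SCF2 replicate 1, and its call ended without SCF3 replicate 2 (adjusted p = 0.0553). Slc4a8 was at least 42.2-fold lower with SCF2, Fbln1 at least 8.91-fold, Fabp9 at least 16.6-fold, and Slc6a3 and Nppb differed by -5.32 and -5.01. With a normexp background and quantile normalization 9 of these 10 differences moved by over 1.5 times, and the call of Spag8 ended (adjusted p = 0.0925). Slc6a3 and Nppb then lay at -3.33 and -2.99. With only the 2 groups compared in the fit, 1 of the 10 calls ended. All 37 cell cycle and DNA replication genes were higher with SCF2, also adjusted over the list alone (adjusted p = 1.44e-20). Lysosome and autophagy, the unfolded protein response, hypoxia and glycolysis, NF-kB targets, proteases, p53 and immediate early genes were lower with SCF2, with 26, 17, 22, 12, 14, 11 and 15 members lower and 3, 2, 4, 2, 4, 5 and 6 higher (26, 17, 22, 12, 14, 11 and 15 lower and 3, 2, 5, 2, 4, 5 and 6 higher adjusted over the list alone). Their adjusted p were 7.65e-06, 0.000233, 0.00038, 0.00386, 0.00682, 0.0161 and 0.0219. With an estimated correlation cell cycle (adjusted p = 0.0024) and lysosome and autophagy (adjusted p = 0.0241) stayed past the threshold, and the other 6 did not, with adjusted p of 0.059, 0.0799, 0.269, 0.0982, 0.059 and 0.18. The call of immediate early genes also ended with probes well above background on all arrays (adjusted p = 0.0621). Calls of scavenger receptors and inflammasome genes were gained with quantile normalization (adjusted p = 0.0259 and 0.037) and with a normexp background and quantile normalization (adjusted p = 0.0142 and 0.0262).

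The 3 comparisons with vehicle share the vehicle arrays, which by itself makes their calls overlap. Past the threshold in the same direction were 7092 genes in SCF1 and SCF3, 3532 higher and 3560 lower, 1806 in SCF1 and SCF2 (959 and 847), 1805 in SCF2 and SCF3 (1031 and 774) and 1587 in all 3 (896 and 691). Independent lists of these sizes would share 1267 and 1394 genes, 275.9 and 251.5, 430.4 and 361.1, and 87.83 and 80.59. The covariance of the fold changes across genes was 0.221 for SCF1 and SCF3, 0.0677 for SCF1 and SCF2 and 0.0823 for SCF2 and SCF3, against 0.00926, 0.00931 and 0.00932 simulated for unchanged groups with shared controls. With the vehicle arrays divided between the comparisons it was 0.207 to 0.215, 0.051 to 0.0629 and 0.0672 to 0.0772. The correlation across genes was 0.825, 0.627 and 0.465 in the same order, against 0.497, 0.498 and 0.498 simulated. No group changed in the simulation, and a correlation also depends on how large the changes of each group are. The simulated correlation is therefore no reference for these values. With the vehicle arrays divided the correlation was 0.726 to 0.78, 0.407 to 0.57 and 0.339 to 0.435. Across genes and corrected for noise, the slope of the SCF1 changes on the SCF3 changes was 0.504, and that of the SCF2 changes was 0.174. Such a slope falls when the changes of different genes disagree, so it does not give the relative size of the changes. Genes higher in SCF3 than in vehicle, higher in SCF3 than in SCF1 and higher in SCF1 than in SCF2, each past the threshold, numbered 1831 and included Arg1, Fabp4 and Trib3. Those lower at each of these 3 steps numbered 1477, Ccnb2 and Bub1 among them. Opposite calls were rarer, with 42 genes higher in SCF1 and lower in SCF3 and 71 the other way among 7205 called in both, 16 and 33 among 1855 for SCF1 and SCF2, and 68 and 94 among 1967 for SCF2 and SCF3.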

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

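The tests of the shared falls, of the cell cycle list and of another difference between the slides were chosen after the result was seen, and the other tests in this part were planned.

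One array lay far from the other 3 of its group in 43 of the 580 groups of 4 that were checked, where chance gives about 1 in 20. These groups share the same arrays and are not independent, so this rate is only a guide. Replicate 4 was the far array in most cases. The replicate number is also the position of the array on its slide, and an effect of position was not tested. The number given is the gap to the nearest array over the range of the group, and all 43 exceed Dixon's 95% critical value for 4 samples. For vehicle, the arrays were vehicle replicate 1 for Xirp1 (0.896), Afdn (0.881) and Tshz1 (0.846), vehicle replicate 2 for Lad1 (0.935) and Insig1 (0.961), vehicle replicate 3 for Slc4a8 (0.876) and Spag8 (0.861), and vehicle replicate 4 for Fbln1 (0.921), Phyh (0.932), Ppp1r15a (0.856) and Ccl9 (0.976). For SCF1, they were SCF1 replicate 1 for Actb (0.849) and Arg1 (0.837), and SCF1 replicate 4 for the 75th percentile of the signal (0.841), Eps8 (0.933), Ttpa (0.851), Vangl1 (0.931), Rrm2 (0.97), Plin2 (0.951) and RT1-DMa (0.873). In the SCF2 group they were SCF2 replicate 1 for Spag8 (0.859) and Ppp1r15a (0.852), SCF2 replicate 3 for Arhgef39 (0.851), Rtkn2 (0.86), Mmp12 (0.884) and Ddit3 (0.875), and SCF2 replicate 4 for Dgkg (0.855), Erbb2 (0.904), Vangl1 (0.861), Lypd8l1 (0.964), Jade2 (0.961), Actb (0.86), Mmp9 (0.884), Nfkbib (0.847), RT1-DMa (0.838) and Cycs (0.86). Among the SCF3 arrays they were SCF3 replicate 1 for Ak9 (0.877), SCF3 replicate 2 for Tnf (0.837), SCF3 replicate 3 for Il1rn (0.832), and SCF3 replicate 4 for Dgkg (0.907), Or1j22 (0.882), Atf4 (0.86) and Olr1 (0.852).

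The effects of SCF2 and SCF3 differed in direction for 68 genes past the threshold in both that were higher in SCF2 and lower in SCF3, and for 94 that were lower in SCF2 and higher in SCF3. SCF2 against SCF3 was past the threshold for each of them, which follows from the opposite calls and adds no support. The negative control spots, which the comparisons do not use, had a mean signal of 58 in SCF1, 56.9 in SCF2 and 56.9 in SCF3, above the 46.7 in vehicle.

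In all 3 fibre groups 26 genes were at least 2-fold lower than in vehicle. Of these 96.2% (exact 95% limits 80.4 to 99.9) were among the dimmest 25% of tested genes over the 16 arrays, and 23 were well above background on no fibre array. A ranking over all arrays favours dim genes when most arrays are fibre arrays, but ranked on the vehicle arrays alone, where the choice of falls works the other way, it was 25 of the 26 genes too. Of the 38 genes at least 2-fold higher in all 3 fibre groups, 65.8% (48.6 to 80.4) were among the dimmest 25% over the 16 arrays as well. On the vehicle arrays alone it was 30 of the 38, a ranking in which the choice of rises favours dim genes. The limits take the genes as independent, which they are not. Dimness is thus not particular to the falls. The 23 genes at background on every fibre array passed the filter on dim probes through the vehicle arrays alone, so the filter builds part of their dimness in. The share of dim genes therefore cannot decide on a lower background on the vehicle slide, which may account for part of the falls. An effect common to the fibres cannot be told apart from such a background, since the most groups on any slide was 1.

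Of the 37 cell cycle and DNA replication genes, 34 were lower in SCF1 and 37 in SCF3. For SCF3 a higher background on the fibre slides is argued against, since the upper quartile of SCF3 minus SCF2, 2 groups of like background, was -0.847 over the members. The scaling of the arrays is argued against for SCF3 as well, since under 3 other scalings the highest upper quartile of SCF3 minus vehicle was -0.893. For the fall in SCF1 neither cause was tested in this way, and the median of SCF1 minus SCF2 over the members was -0.539. Another difference between the slides cannot be told apart from the fibres, since the most slides of any group was 1. An effect of the fibres stays open beside the slides, as untested.

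The fold changes of SCF1 and SCF3 against vehicle went together across genes. The shared vehicle arrays are argued against as the whole cause, since SCF1 minus vehicle and SCF3 minus SCF2, which share no array, correlated at 0.645 across genes. A trend with signal is argued against too, since the correlation was 0.652 after the median of each of 20 bins of mean signal was removed. Another difference between the slides stays open, since the most slides of any group was 1. A response common to SCF1 and SCF3 stays open beside it, as untested.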

How the results depend on the processing

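The runs without SCF3 arrays 3 and 4, the list tests with the array number as a block, the array median, normexp or the stricter filter, and all alternatives of the 2-fold counts were chosen after seeing the data. The cause was not tested for any value below, except where the filter or threshold itself sets how many genes are tested or called. In the order SCF1, SCF2 and SCF3 against vehicle, SCF1 against SCF2, SCF1 against SCF3 and SCF2 against SCF3, genes past the threshold of at least 2-fold numbered 111, 17, 785, 44, 132 and 592 with normexp and quantile normalization (79, 13, 423, 35, 15 and 255 of them higher), and genes of at least 1.5-fold 1856, 444, 4846, 1052, 1942 and 3973. With no filter on dim probes there were 6940 genes for SCF2 (873 of at least 2-fold, 649 of them higher), 18798 for SCF3 (3958, 2775 higher), and 1347 (819 higher) and 785 (145 higher) of at least 2-fold for SCF1 and SCF1 against SCF3. With probes well above background on all arrays, 246, 46, 112 and 287 of at least 2-fold were left for SCF1, SCF2, SCF1 against SCF2 and SCF1 against SCF3 (185, 36, 80 and 60 of them higher), a filter that by itself removes genes at background in 1 of the groups. Array weights gave 4198 genes for SCF2 and 8750 for SCF1 against SCF2, and an adjusted p under 0.01 gave 871 (74 of at least 2-fold, 44 of them higher) and 3499. Leaving out 1 array gave 1613 (without vehicle replicate 2) to 3158 (without SCF3 replicate 4) genes for SCF2. With the vehicle arrays divided, SCF1 and SCF2 shared 1130, 920, 816, 532, 823 and 661 genes, and SCF2 and SCF3 1064, 1325, 559, 936, 723 and 918. Lists called with an estimated correlation numbered 5, 1, 3, 4, 1 and 2. The direction split of the calls moved most with the array median, from 47.8% to 59.3% higher in SCF1, 54.5% to 38.8% in SCF2, 50.2% to 71.6% in SCF1 against SCF2 and 48% to 62% in SCF1 against SCF3, and without a filter, to 64.3% in SCF1, 79.5% in SCF2 and 65.8% in SCF3.

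With normexp and quantile normalization Fbln1 in SCF2 (-0.0379) and Actb in SCF1 (-0.00324) reversed. For SCF1 minus SCF3 and SCF2 minus SCF3, normexp and quantile normalization reversed Gapdh (0.0868 and 0.0788), B2m (0.0588 and 0.0185) and Ctsd (0.0166 and 0.0302), and quantile normalization alone Gapdh (0.0699 and 0.0334), B2m (0.0486 and 0.0268) and Ctsd for SCF1 minus SCF3 (0.00821). Of the 864 changes checked, those of part of the genes under the naming rule in the 6 comparisons, 776 kept direction and side of the threshold with normexp and quantile normalization, 812 with quantile normalization, 808 with the array median, 844 with no filter, 827 with array weights and 813 with only the 2 groups compared, as did 13446 of 13824 with 1 array left out. The value table gives no p-value and is made from the same signal, so it decides nothing here. Of 150 list results, 115 did so with an estimated correlation and 123 with quantile normalization.

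With the array number as a block there were 8343, 2424, 12548, 5781, 9058 and 11678 genes, and 13657 for any difference among groups, and of the list calls only that of inflammasome genes in SCF1 against SCF3 changed. With 1 array left out, heat shock was gained in 7 of the 16 fits in SCF1 and 5 in SCF2, alternative activation in 7 in SCF1 and 4 in SCF3, and 9 other list calls in 1 or 2 fits each. Slide or scan date as a block was not run, since each slide held 1 group and the model already holds the group.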

Other observations

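The numbers of other splits and the test of SCF2 and SCF3 in this part were planned.

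Other splits of the same arrays were counted to see whether chance can be excluded for the numbers of genes past the threshold, the real split among them. For SCF1 against vehicle, 1 of the 35 splits of the 8 arrays into 4 and 4 gave as many genes as the 8330 of the real split, and the highest other gave 3. For SCF2 it was 1 of 35 with 2479 genes and 9 at most elsewhere, and for SCF3 1 of 35 with 12455 and 184. Between fibres it was 1 of 35 each, with 5766 genes against at most 1 for SCF1 and SCF2, 9025 against 30 for SCF1 and SCF3, and 11554 against 1 for SCF2 and SCF3. For any difference among the 4 groups it was 1 of 100 drawn splits, with 13638 genes against at most 3. Chance in the grouping of the arrays can be excluded for each of these numbers. A difference between the slides stays open, as does one between single cultures, since the labels give 1 sample per group and do not say whether its arrays come from separate cultures.

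For the number of gene lists called, as many as in the real split came from 4 of 35 splits in SCF1 against vehicle (9 real, 10 the highest other), 3 of 35 in SCF2 (9 and 10), 4 of 35 in SCF3 (8 and 9), 7 of 35 for SCF1 against SCF2 (7 and 8) and 2 of 35 for SCF2 against SCF3 (8 and 8). Chance cannot be excluded for these numbers of lists. For SCF1 against SCF3 it was 1 of 35 (10 and 8), so chance in the grouping of the arrays can be excluded for this number taken singly. Of the other 34 splits, 16 keep 3 arrays of each group together and so hold part of the real difference, and among the 18 that mix the groups evenly the highest number of lists was 1, 2, 2, 2, 3 and 2 in the order SCF1, SCF2 and SCF3 against vehicle, SCF1 against SCF2, SCF1 against SCF3 and SCF2 against SCF3.

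A hypothesis was that SCF2 holds a weaker form of the SCF3 change. It predicts a correlation across genes of SCF2 minus vehicle with SCF3 minus SCF1, which share no array, of over 0.3, and its absence one under 0.1. The correlation was 0.137, so the test decides neither way, and SCF2 may share part of the SCF3 change without following it throughout.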
